A study of Caenorhabditis elegans with 4 samples.

How the data were processed

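RNA bound after UV crosslinking was measured by eCLIP, a sequencing assay of RNA that comes down with an immunoprecipitated protein, in whole young adult Caenorhabditis elegans. Per the labels' protocols, worms were kept at 25 °C and irradiated at 1.2 mJ/cm2. The series has 4 libraries. There are 2 immunoprecipitations from worms whose gene F22D6.2 carries a 3xFLAG tag (MSTR-1::FLAG), which the design text calls biological replicates. The other libraries are 1 immunoprecipitation from untagged N2 worms and 1 size-matched input of the tagged genotype.

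The authors deposited 2 peak tables, one for MSTR-1 CLIP and one for N2 CLIP. Per the submitters' processing notes, cutadapt, UMI-tools, STAR and deepTools were used. Their versions, the peak caller, its thresholds, the genome build and the annotation are not given in the sources used here. Each library column of the deposited tables holds a signal, the reads of each peak divided by 1 size factor per library. Each value was a whole multiple of a fixed step within 0.02 of a read for 100% of values in each column, so whole reads were recovered by dividing by that step. The size factors were 0.921 and 1.53 for the CLIP libraries and 0.693 for the input in the MSTR-1 table, and 0.591 for N2 CLIP and 1.69 for the input in the N2 table. The fold that the authors deposited in the MSTR-1 table is the sum, not the mean, of both CLIP columns over the input, so a listed fold of 1 is a mean CLIP value of 0.5 of the input's. In the N2 table the deposited fold is N2 CLIP over the input. No adjusted p was used, since the tables as used here carry none. The columns do not say which CLIP library is replicate 1 or 2, so they are called library A and library B. The control column of both tables was read as the input, the only library of that kind. At 75 of the 227 paired peaks the recovered input reads were identical in both tables.

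The plan made before the data were examined was to run edgeR's quasi-likelihood test on counts. As the values are scaled, limma 3.58.1 in R 4.3.3 was used for the main comparison, on log2(scaled reads + 1) with a trend of the variance on the level and Benjamini-Hochberg adjustment at 0.05. A log2 change on this scale understates the change of peaks with few reads. The lone input was assumed to vary like the CLIP libraries, and no p-value holds a spread between inputs. With the trend, limma's spread between the CLIP libraries was in effect pooled over peaks of similar level. A peak over hlh-11 with 1 and 36 CLIP reads had an SE of 2.32, and one over mig-6 with 3 and 16 had 2.36. The limma p-values therefore do not measure how well the CLIP libraries agree at a single peak. edgeR 4.0.16 on the recovered reads and DESeq2 1.42.0 were run beside it. In simulated tables of 2664 peaks with 200 changed, limma called 4.48%, 17.9% and 51.5% of peaks changed 2-fold, 4-fold and 8-fold, with 4 calls among unchanged peaks. edgeR called 0%, 8.96% and 36.4%, with 0 such calls.

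Peaks were named by position with the gene table of assembly WBcel235, on either strand, leaving out 15363 piRNA genes. That assembly was tested by sliding the peaks along it, since the build of the peaks is not given in the sources used here. At a shift of 0 nt 61 peaks held at least 90% of a short RNA gene, against at most 27 at shifts of 20 nt or more. Of 2664 MSTR-1 peaks, 2404 lay over 1 gene, 202 over 2, 26 over 3 or more and 32 over none. A peak over exactly 1 gene is called that gene's own peak. Strand was not used for naming. All 7 mitochondrial MSTR-1 peaks are listed on the minus strand, although worm mitochondrial genes are known to be encoded on the plus strand of the reference, and all 517 genes with 2 or more own peaks had them on 1 strand. Peaks were intersected with bedtools 2.31.1 on the same strand with at least 1 bp shared. Exact Clopper-Pearson 95% intervals of shares cover counting error only. The 95% intervals of folds are exact Poisson intervals of the input reads alone, and leave out the counting error of the CLIP reads. A fold over an input of 0 reads is given as a lower bound against 3 reads.

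The 16 gene lists were fixed before the data were examined. Each was tested with Fisher's exact test, two-sided, over 19983 protein-coding genes, adjusted over 16 lists. The genes counted had at least 1 own MSTR-1 peak that no N2 peak overlaps, whether or not other peaks of the gene did. The shift of a list is the median over its genes of log2 CLIP over input, set beside 10000 random lists of the same size matched on level. A simulated list filled with 15 members was called and 0 other lists were. Genes were named by a rule fixed in advance. It took the 20 genes with the highest deposited fold at an own peak without N2 overlap and with both CLIP libraries above the input, the 5 genes with most such peaks, the 5 genes with the highest N2 fold (peaks without an input read rank first, by their N2 reads), F22D6.2, up to 4 members per list, and the 10 shared peaks with the highest fold. Genes named outside that rule are said to be chosen after their values were seen.

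The number of N2 reads expected at an MSTR-1 peak is the number N2 CLIP would have at the same fold over the input. The alternatives tried were other scalings, read minimums, pseudocounts, stricter folds, other overlap rules, other gene backgrounds and 1 CLIP library at a time. Peaks were not assigned to transcript regions and no sequence motifs were searched, because no genome sequence or exon annotation was used here. The analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.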

Results

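The MSTR-1 table lists 2664 peaks with a median length of 164 nt, and the N2 list has 310 peaks with a median length of 122 nt. Reads inside MSTR-1 peaks numbered 2438775 in CLIP library A, 3592308 in library B and 408945 in the input. N2 CLIP had 934439 reads inside its peaks. Ribosomal RNA genes on chromosome I held 91.9% and 92.3% of these reads in libraries A and B and 68.6% in the input over the same peaks. Over the N2 peaks they held 98.5% in N2 CLIP and 92.5% in the input. Most peaks were shallow, with a median of 15 and 24 reads per peak in libraries A and B and 8 in the input. No read of the input fell in 213 of the 2664 peaks.

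The MSTR-1 immunoprecipitations ranked the peaks alike. Across 2664 peaks, which are not independent replicates, Pearson's r of log2(scaled reads + 1) was 0.85 and Spearman's rho 0.79, and the median absolute difference between the libraries was 0.48. Among 1094 peaks with at least 50 reads in both libraries together r was 0.96. The libraries differed at least 8-fold at 124 peaks, 115 of them higher in library B, and library A had no read at 107 peaks against 3 for library B.

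Which RNAs were enriched over the input was asked of each peak. Cuticle collagen, histone and muscle transcripts and ribosomal RNA lay above the input, and ribosomal protein and vitellogenin transcripts lay below it. Of 2664 peaks, 337 were higher than the input and 47 lower (limma, adjusted p under 0.05), and edgeR on the recovered reads gave 253 and 38. The lower peaks had mean folds of 0.50 to 0.66, and the list holds no peak under a mean fold of 0.5. Every listed peak has a deposited fold above 1 over this same input, so the calls describe already selected peaks. Peaks named for their folds were chosen on the same values, so their p-values and bounds come after that choice. The direction against the input rests on the scaling. The median log2 CLIP over input of all peaks was 0.53 with the authors' size factors, 0.16 with DESeq2's, 0.12 with TMM and -1.40 with column totals, and the calls were 95 higher and 93 lower with DESeq2, 118 and 150 with TMM and 50 and 1111 with column totals. limma without a trend called 0 in either direction, with 380 peaks at an unadjusted p under 0.05. Gene groups are therefore also given relative to the median of all 1347 genes with an own peak, 0.57 on the log2 scale.

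**Figure D1:**
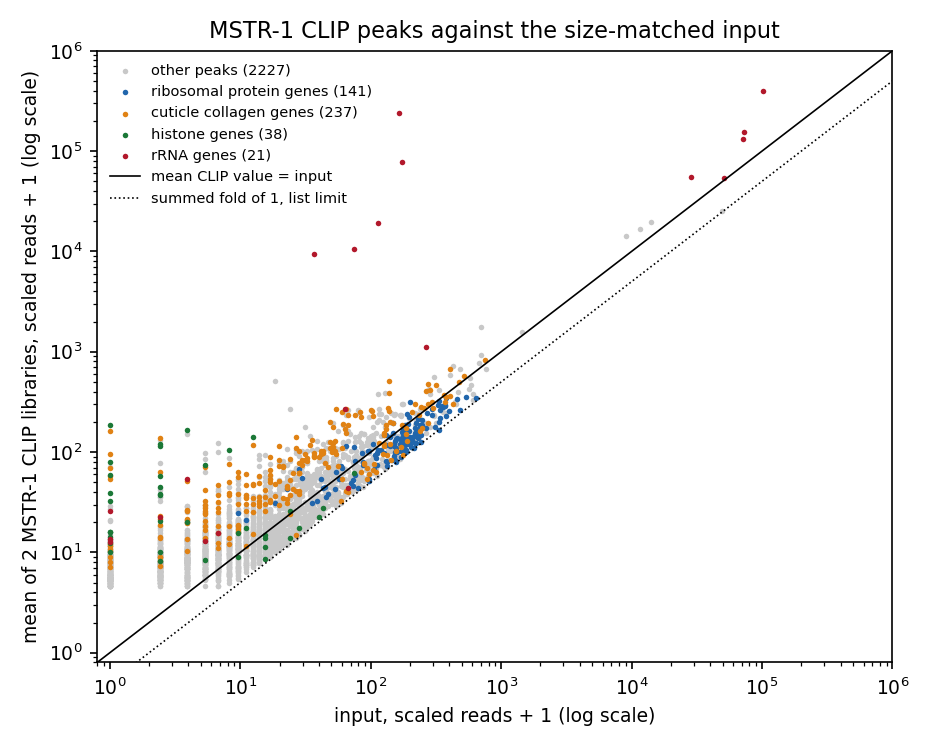
Mean scaled reads of the 2 MSTR-1 CLIP libraries (vertical, log scale) against the size-matched input (horizontal, log scale), 1 point per peak, with 1 added to each value, for 2664 peaks. Histone (38 peaks, green) and collagen (237, orange) peaks lie mostly above the line of equality, ribosomal protein peaks (141, blue) mostly between it and the dotted limit of the list, and rRNA peaks (21, red) include the points at the highest values and some shallow ones.

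Cuticle collagens, the structural proteins of the worm's exoskeleton, gave the largest group of enriched peaks. Among their own peaks 95 were higher than the input, 3 lower and 83 did not pass (110 and 7 adjusted over the list alone), and TMM gave 30 higher and 10 lower and column totals 7 and 63. The median over 69 collagen genes was 2.67-fold over the input and 0.84 above that of all genes on the log2 scale, higher than 100% of 10000 matched random lists. Among the named collagen peaks, that over col-117 (chromosome IV, 8823411 to 8823735) had the highest bound, with 165 and 213 reads in the CLIP libraries and 0 in the input, at least 36.8-fold higher (log2 change 7.31, SE 0.45, limma adjusted p = 5.43e-55, edgeR adjusted p = 3.05e-21). Peaks over col-144 and col-13 were at least 15.8-fold and at least 13.2-fold higher than the input. The placement of reads among collagen genes of similar sequence was not examined, so values of single collagens are uncertain. The gene col-12, which lies near col-13 and was chosen after its values were seen, had 132 input reads and a mean fold of 2.68. The collagen col-181 had a peak that was higher (mean fold 3.14) and another that was lower (0.52), chosen after its values were seen.

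Replication-dependent histone genes, which encode the core proteins of nucleosomes, had 19 of 36 own peaks higher and 0 lower (20 and 0 adjusted over the list alone). They had 14 higher and 0 lower with TMM, and 14 higher and 9 lower with column totals. Their median over 25 genes was 8.48-fold with the pseudocount of 1 and 3.05-fold with the 4 genes without an input read at their bound. It was higher than that of 100% of matched random lists. Peaks over his-45, his-47 and his-15 were at least 18.2-fold, 13.6-fold and 7.32-fold higher than an input of 0 reads. Histone genes and actin genes have near-identical copies, and the placement of reads among copies was not recorded, so values of single members are uncertain.

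Muscle transcripts had 24 of 110 own peaks higher and 0 lower (30 and 0 adjusted over the list alone), with 2 higher and 0 lower under TMM and 2 and 57 under column totals. The median over 27 genes stood 0.22 above that of all genes, higher than 98.4% of random lists, and 0.66 above in library A alone against 0.090 in library B alone. The peak over act-3, an actin, was at least 16.18-fold higher (62 and 111 reads against 0 in the input). Peaks over ttn-1 and unc-89, genes of giant muscle proteins, had bounds of 2.42-fold and 2.14-fold and limma adjusted p of 0.14 and 0.51. Major sperm proteins, the cytoskeletal proteins that move nematode sperm, had 5 of 32 peaks higher and 0 lower (5 adjusted over the list alone), 0 of either with TMM and 7 lower with column totals. Their median was 0.43 above that of all genes and above 98.9% of random lists (0.69 above in library A alone). The peak over msp-79 stood at 11.02-fold (16 and 22 reads against 1, 95% interval from input counting alone 1.98 to 435, limma adjusted p = 0.017). That peak did not pass edgeR's test (adjusted p = 0.11 with the authors' scaling and 0.18 with TMM). How reads were placed among the major sperm protein genes was not examined, so values of single members are uncertain.

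Cytosolic ribosomal protein transcripts lay at the other end. Of 122 own peaks 23 were lower than the input, 3 higher and 96 did not pass (33 and 3 adjusted over the list alone), TMM gave 59 lower and 0 higher, and column totals 117 and 0. The median over 72 genes was 0.79-fold over the input and -0.92 relative to all genes, below all 10000 matched random lists, and -0.53 in library A alone. The peaks of rpl-7 with a call had mean folds of 0.53, 0.54 and 0.51, chosen after their values were seen. The 3 higher peaks were over rps-27 (2.44-fold), rpl-41.2 (1.59-fold) and rpl-29 (1.80-fold). Vitellogenins, the yolk proteins made in the intestine, had 5 of 19 peaks lower and 0 higher (8 lower adjusted over the list alone), 11 lower with TMM and 16 with column totals, with a median of 0.73-fold over 4 genes, -1.03 relative to all genes and -0.68 in library A alone. Translation factors had 4 of 46 peaks lower and 0 higher (4 lower adjusted over the list alone), 10 lower with TMM and 35 with column totals, a median of -0.77 relative to all genes and a percentile of 2.98.

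None of the own peaks over oocyte and maternal regulators (14), chaperones (35), splicing factors (18), germ granule factors (11) or meiosis genes (1) passed limma's threshold in either direction. At an unadjusted p under 0.05 there was 1 lower peak each for oocyte and maternal regulators, chaperones and germ granule factors, and TMM called 1 lower peak each for chaperones and germ granule factors. Column totals placed 12, 25, 8, 7 and 0 of these below the input. Relative to all genes their medians were -1.04 for oocyte and maternal regulators, -0.85 for chaperones, -0.76 for splicing factors and -0.71 for germ granule factors, at percentiles of 0.18, 0.41, 1.21 and 7.12. They were -0.67 for oocyte and maternal regulators, -0.43 for chaperones and -0.22 for germ granule factors in library A alone, and -0.38 for splicing factors in library B alone. Intestinal genes had 2 of 33 peaks higher and 0 lower, 0 and 3 with TMM and 0 and 22 with column totals, and a median of -0.34 at the percentile 32.6 (-0.015 in library A alone). Sperm genes other than MSP had 1 of 11 higher, over ssp-9 (at least 4.50-fold), 7 lower with column totals, and a median of -0.35 at the percentile 36.7 (-0.094 in library A alone). The list of neuronal genes had 2 of 9 peaks higher, over nlp-33 (2.99-fold) and nlp-24 (3.70-fold), 1 higher with TMM and 2 lower with column totals, and a median of 0.70 at the percentile 96.0 (1.06 in library A alone). Its members with peaks included nlp-27, nlp-28, nlp-29 and nlp-34, of a peptide cluster known for antimicrobial peptides of the epidermis. N2 peaks overlapped 4 of the 9 peaks of this list, among them those over nlp-33 (N2 fold 4.70) and nlp-24 (N2 fold 8.95). The single mitochondrially encoded messenger peak, over COX1, was 24.1-fold higher (32 and 53 reads against 1). Its 95% interval from input counting alone was 4.32 to 951 (limma adjusted p = 2.74e-08, edgeR adjusted p = 0.0002).

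**Figure D2:**
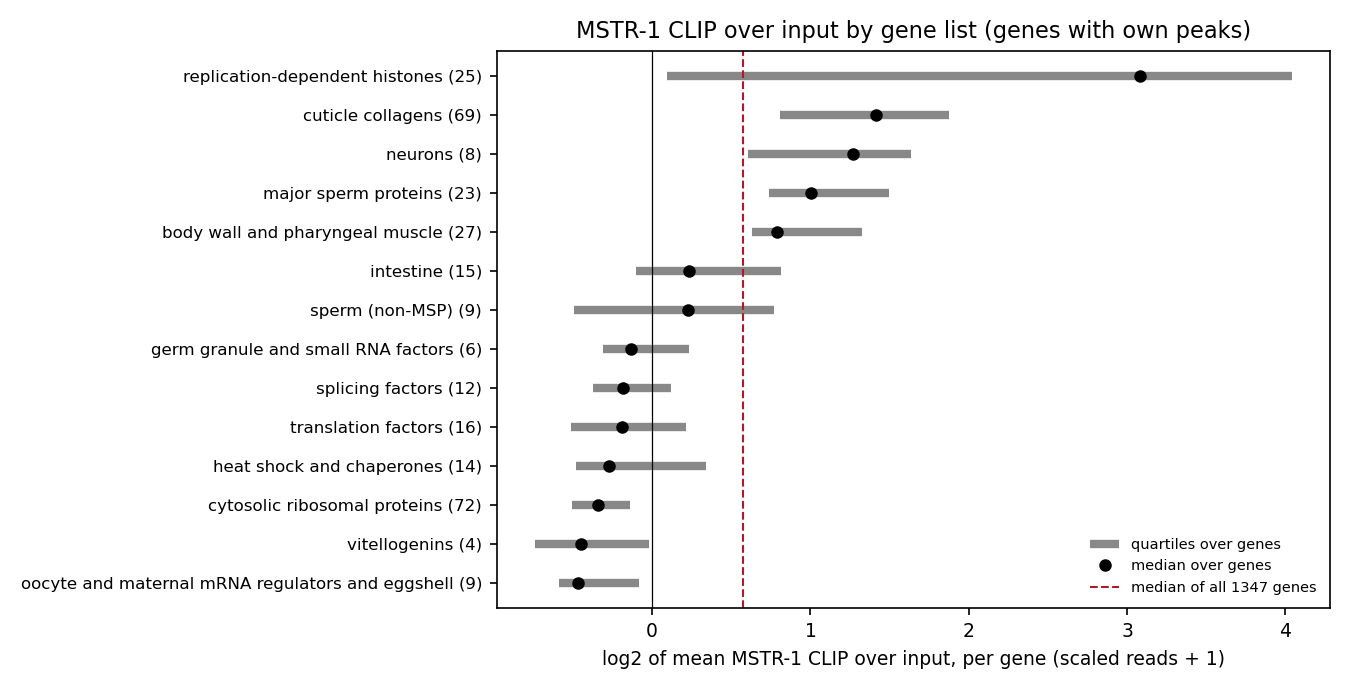
Median (points) and quartiles (bars) over genes of log2 mean MSTR-1 CLIP over input for 14 gene lists, with the number of genes with own peaks in brackets and the median of all 1347 genes as a dashed line. Histones (3.08) and collagens (1.42) lie highest, and ribosomal proteins (-0.34), vitellogenins (-0.45) and oocyte and maternal regulators (-0.47) lowest.

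The rule for named genes also gave genes outside the lists. Peaks over pck-1 (phosphoenolpyruvate carboxykinase, an enzyme of gluconeogenesis) and acs-2 (an acyl-CoA synthetase of fat oxidation) were at least 6.04-fold and 4.58-fold higher than an input of 0 reads, with limma adjusted p of 4.03e-06 and 0.00045. A mitochondrial rRNA peak, over KEF34_r02, was at least 5.78-fold higher, ccg-1 at least 3.42-fold and gfi-1 at least 3.22-fold. In that order, edgeR's adjusted p with TMM were 0.071, 0.083 and 0.098, so these calls were lost with TMM. The peaks over mop-25.1, hlh-11, T21C9.9, sea-2 and mnk-1 had bounds of 2.79-fold to 2.89-fold and did not pass limma's threshold. Of 1130 peaks eligible under the rule, the largest numbers on single genes were 13 on emb-9 and 12 on let-2, the genes of basement membrane type IV collagen. Next came mig-6 (10), a papilin of the basement membrane, vab-10 (10), a spectraplakin, and icl-1 (9), the glyoxylate cycle enzyme. The tagged gene itself, mstr-1 (F22D6.2), had 1 peak (chromosome I, 7081372 to 7081527) with 21 and 29 reads against 10 in the input, and no N2 peak. Its mean fold was 1.45 (95% interval from input counting alone 0.79 to 3.02, limma adjusted p = 0.69). With column totals its log2 change was -1.55 (edgeR adjusted p = 0.047).

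Gene lists were also counted by membership, whatever the height of the peak. Among 1264 protein-coding genes with at least 1 own MSTR-1 peak that no N2 peak overlaps, 13 of 16 lists were over-represented. Of these genes 115 also had an own N2 peak, so the set is not free of N2 background. The odds ratio was 78.0 for ribosomal proteins (65 of 78 genes), 43.3 for major sperm proteins (23 of 31), 31.5 for muscle (25 of 37) and 8.94 for cuticle collagens (64 of 175), with adjusted p of 3.90e-64, 4.25e-21, 4.02e-21 and 1.82e-31 by Fisher's exact test. It was 29.7 for vitellogenins, 15.99 for translation factors, 9.97 for chaperones, 9.76 for the intestine, 7.47 for splicing factors, 7.06 for histones, 4.79 for oocyte regulators and for other sperm genes and 4.05 for germ granule factors. Meiosis (0.49), neurons (0.56) and mitochondrially encoded genes (1.35) did not pass. With random genes matched on gene length the same 13 lists passed. Ribosomal proteins had 10.99 times the expected number of genes with a peak, major sperm proteins 10.4, muscle 9.15 and collagens 5.57, with Mantel-Haenszel odds ratios over bins of gene length of 72.5, 43.9, 31.5 and 9.60. Among 202 genes with an own N2 peak, ribosomal proteins (29.7), muscle (38.1) and collagens (19.5) passed. With genes that have only MSTR-1 peaks set against genes with an N2 peak, collagens (odds ratio 0.27, adjusted p = 3.35e-05) and muscle (0.29, adjusted p = 0.029) were more frequent among N2 genes. Counted from peaks above the input in 1 library alone, oocyte regulators lost their call with either library, germ granule factors with library B alone (adjusted p = 0.058) and splicing factors with library A alone (0.089). For ribosomal proteins the odds ratio was 181.9 with all MSTR-1 peaks and 138.3 with any overlapping gene. It was 5.59 with library B alone above the input, 9.55 with library A alone and 6.38 with their mean above it. It fell to 0.86 at a deposited fold of at least 4 (adjusted p = 1). At that fold vitellogenins, chaperones, splicing factors, oocyte regulators, germ granule factors and other sperm genes also lost their calls, with odds ratios under 1 for oocyte regulators and splicing factors. With library A alone above the input, the odds ratio was 11.2 for vitellogenins and 9.20 for translation factors, and with library B alone it was 5.89 for chaperones. No expression level was used as the background, so an odds ratio mixes expression with binding.

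N2 worms carry no FLAG tag, so their CLIP peaks are the background of the immunoprecipitation. MSTR-1 peaks with an N2 peak included histone, actin, collagen and rRNA loci. Of 2664 MSTR-1 peaks 233 overlapped an N2 peak (8.75%, 95% interval 7.70 to 9.88), and of 310 N2 peaks 227 overlapped an MSTR-1 peak (73.2%, 67.9 to 78.1). Among the 337 MSTR-1 peaks called higher than the input by limma, 107 overlapped an N2 peak. At the 223 pairs with input reads in both tables the N2 fold exceeded the MSTR-1 mean fold at 177 (79.4%), with median folds of 3.15 and 1.93, but at 72 with column totals. The N2 list holds no peak below the input, which favours N2 in this count. A pair needed only 1 shared bp, and input reads were equal at 75 of 227 pairs, so most paired peaks differed in extent. N2 CLIP is a single library, so this comparison has no replicate check. N2 folds are taken over an input of the tagged genotype, so any difference in RNA level between the genotypes would enter them. At his-58 a pair of shared peaks had 177 and 266 MSTR-1 reads with 0 in the input, and 109 and 184 with 1. The shared rRNA peaks with the highest folds were over rrn-3.56 (mean fold 1486), annotated as an rRNA pseudogene, and rrn-1.1 (448). The rrn-3.56 peak had 113 input reads, and the placement of reads between rrn-3.56 and rrn-3.1 was not examined. Reads of both 18S copies lay on rrn-1.1 at 17.04% in library A, 15.5% in library B and 16.7% in N2 CLIP but 0.16% in the input, and both copies together stood at 3.30-fold in MSTR-1 CLIP. Shared peaks over ZC434.9 and F01D5.10 had 0 and 1 input reads. A small shared peak in rrn-3.1 (chromosome I, 15068089 to 15068238), with 18 and 9 MSTR-1 reads, had 0, while other shared rrn-3.1 peaks, listed on the opposite strand, had 49143 to 54201 input reads. Among N2 peaks over 1 gene without an input read, those with the most N2 reads (22 to 30) were over ZK180.6, hrg-11.3, pat-2, snx-14 and ptr-21, at least 28.6-fold at ZK180.6. The highest N2 fold with input reads, 2212, was over rrn-3.56.

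The share of MSTR-1 peaks with an N2 peak followed the number of N2 reads expected there. At the MSTR-1 fold, 1995 of 2664 peaks would have given under 11 N2 reads, the fewest in any N2 peak (1619 with column totals). The share rose from 1.71% where under 5.5 reads were expected to 50% (35.2 to 64.8) where over 88 were. For peaks with a mean fold of at least 2 it rose from 1.88% to 100% (15 of 15 peaks, 78.2 to 100). Most of these 15 peaks lay over rRNA genes.

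**Figure D3:**
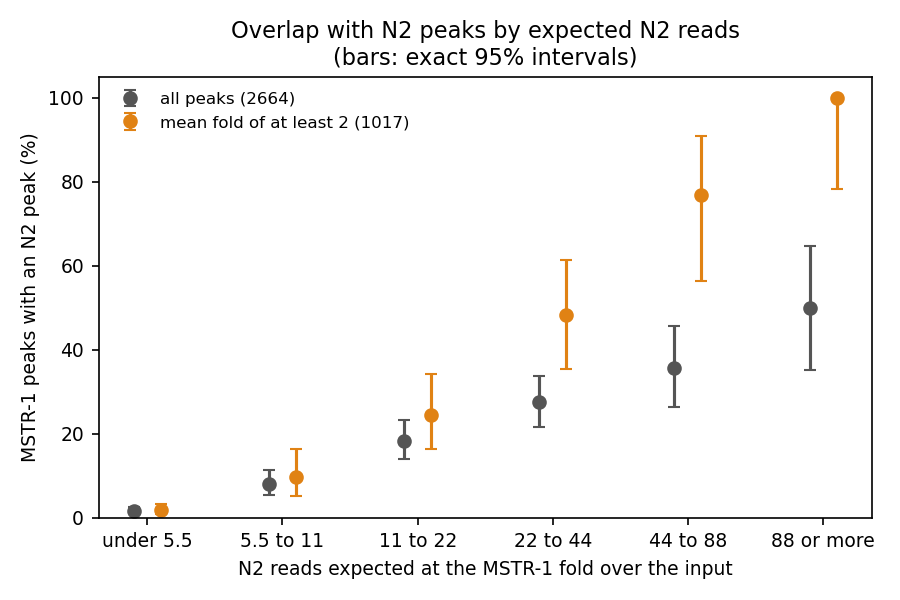
Percent of MSTR-1 peaks with an overlapping N2 peak (vertical) by the number of N2 reads expected at the MSTR-1 fold (horizontal, 6 classes), for all 2664 peaks (grey) and the 1017 with a mean fold of at least 2 (orange), with exact 95% intervals as bars. Both series rise from under 2% in the lowest class, to 50% for all peaks and to 100% for the others.

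By gene class, protein-coding peaks made up 2494 of 2664 MSTR-1 peaks (93.6%) and 268 of 310 N2 peaks (86.5%, Fisher's exact test, adjusted p = 8.13e-05). rRNA genes had 21 MSTR-1 peaks (0.79%) and 16 N2 peaks (5.16%, adjusted p = 1.79e-06). These tests compare 2 lists and not replicated conditions. The shares depend on list length, and 1995 of 2664 MSTR-1 peaks would have given under 11 N2 reads. In MSTR-1 CLIP 15 of the 21 rRNA peaks were higher than the input, as were 9 of 52 tRNA peaks, 5 of 33 snoRNA peaks and 0 of 7 snRNA peaks. The lists did not differ past the threshold in tRNA (52 and 11), snoRNA (33 and 4), snRNA (7 and 0), pseudogene (16 and 3) or intergenic (32 and 7) peaks. Chromosome III held 433 MSTR-1 peaks (16.3%) and 30 N2 peaks (9.68%, adjusted p = 0.015). The protein-coding difference did not pass with each gene counted once (adjusted p = 0.12) or with a deposited fold of at least 4 (0.050), nor did chromosome III (0.075 and 0.63).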

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

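All tests in this part were chosen after the results were seen, except the comparison of collagens with ribosomal proteins in N2, whose prediction was written first.

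At 28 of the shared pairs both MSTR-1 libraries lay below the input while N2 CLIP lay above it. The median folds there were 0.73 in MSTR-1 CLIP and 1.28 in N2, and 8 of the 28 had an N2 fold of at least 2. Genes of the ribosomal protein list held 7 of them, and 1 lay over rplp-2.2, a ribosomal stalk protein gene whose symbol that list does not take. With column totals, N2 CLIP lay above the input at 0 of the 28. The difference was not tested, N2 CLIP is 1 library, paired peaks can differ in extent and the N2 table holds no peak below the input.

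High folds fell on rrn-1.1, with 196 input reads against 125830 on its near-identical copy rrn-1.2, and on 26 peaks outside rRNA genes with at least 50 reads in each MSTR-1 library and at most 5 in the input, 9 over histones, 9 over collagens, 4 over act-3 and 4 elsewhere, 1 of them between rRNA genes on chromosome I. MSTR-1-dependent binding as the whole cause is argued against at rrn-1.1, where the N2 fold was 1.89 times the MSTR-1 fold (0.90 with column totals). Reads placed on different copies in the input and in CLIP may account for rrn-1.1 and act-3: the share of both 18S copies' reads on rrn-1.1 was at least 99.4 times as large in the CLIP libraries, N2 included, as in the input, that of act-1, act-2 and act-3 reads on act-3 at least 21.05 times as large in the MSTR-1 libraries (14.4% in N2 CLIP against 1.04% in the input), and the 3 actins together stood at 1.74-fold. At the 26 peaks MSTR-1 dependence stays open. At the 6 that N2 peaks overlap, the N2 fold was 0.43 to 1.67 times the MSTR-1 fold with a median of 0.74, but 0.21 to 0.79 with a median of 0.36 with column totals, and as an N2 peak holds at least 11 reads, being listed alone gives 0.25 to 0.54. For the 20 without an overlap N2 reads are not given, and 8 of these would have had at least 22 N2 reads at the MSTR-1 fold.

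Collagens stood above and ribosomal proteins below the median of all genes, and N2 CLIP showed the same order. At 25 collagens and 17 ribosomal proteins with own peaks in both tables, the difference of their medians in log2 fold was 1.70 in MSTR-1 CLIP and 1.85 in N2, a ratio of 1.09 (N2 difference, permutation p = 0.0004, two-sided, 100000 permutations across genes). The order was therefore not particular to MSTR-1 CLIP at these genes. An N2 peak holds at least 11 reads and lies above the input, so its lowest possible fold depends on its input reads. Collagen and ribosomal protein peaks differ in input reads, and the permutations applied no such limit. These values therefore do not settle whether MSTR-1-dependent binding adds to the order. The collagen minus ribosomal protein difference in log2 MSTR-1 over N2 reads was -0.20 (-0.30 in library A and -0.06 in library B). Only genes with an N2 peak could enter, paired peaks can differ in extent, and the value does not show whether MSTR-1 binds either group. Both folds use the same input library, so a background of the immunoprecipitation that favours collagen RNA and a shortage of it in this 1 input may each give the order. Counting noise alone gave at most 0.35 in 1000 simulations, which did not apply the limits for listing an N2 peak. For collagens without an N2 peak the question of MSTR-1-dependent binding stays open as well.

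N2 peaks covered few MSTR-1 peaks, and a low number of N2 reads could account for much of this. Among peaks with a mean fold of at least 2, the share with an N2 peak was 20.6 times as high where at least 22 N2 reads were expected (65 of 103) as where under 11 were (25 of 816). No N2 peak holds under 11 reads, and the expected number is the MSTR-1 signal rescaled. This contrast therefore does not separate few N2 reads from MSTR-1-dependent binding at peaks of low signal. The lower bar of the MSTR-1 list could also contribute, since with at least 22 expected reads the share was 4.83 times as high at peaks whose mean lay above the input (107 of 223) as at the rest (15 of 151). For 38 peaks with at least 22 expected reads and a mean fold of at least 2, the lack of an N2 peak stays open. They include peaks over col-10, col-12 and his-57. The N2 peak threshold is not given in the sources used here, and the share still rose with the number of expected reads. It was 48.4% at 22 to 44 expected reads, 76.9% at 44 to 88 and 100% at over 88, where most peaks lay over rRNA genes. Whether MSTR-1-dependent binding at collagen transcripts adds to these 38 peaks cannot be told apart from chance. An N2 peak lay over 22 of 43 collagen peaks and 27 of 43 other protein-coding peaks (Fisher's exact p = 0.38).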

How the results depend on the processing

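The main limma test was not in the plan and was chosen once the values proved to be scaled. edgeR with the authors' scaling is the test planned for counts, run here on recovered reads. Alternatives named here as added were chosen after seeing the data: limma without a trend, other pseudocounts for the enrichment test, peak sets without rRNA or with a mean above the input, any overlapping gene, column totals for the N2 table, pairs by library, Mantel-Haenszel odds ratios over bins of gene length, and the list shifts by library or read minimum. No paired analysis was possible because the input and N2 CLIP have no numbered replicates and the columns carry no replicate number. Adjusted p under 0.01, transcript regions and k-mers were not run, since the tables used here hold no adjusted p and no genome sequence or exon annotation was used. Genes were matched on gene length in place of exonic length.

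With a median of 8 input reads per peak and 1 input library, folds of single peaks are imprecise, and a minimum of 50 reads gave 350 higher and 64 lower peaks. The 337 higher and 47 lower peaks became 118 and 150 with TMM, 50 and 1111 with column totals, 95 and 93 with DESeq2 (1653 peaks without an adjusted p), and 0 and 0 in limma without a trend. A deposited fold of at least 4 gave 0 lower. TMM and column totals move the median of all peaks by construction, and the cause of the other changes was not tested. Peaks above the input numbered 1412 in both libraries, and 1680 to 1811 in 1 library alone.

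The share of MSTR-1 peaks with an N2 overlap (8.75%) was 5.14% with 0.5 of the peak required, 10.6% within 100 bp, 20.5% by gene and 10.4% for peaks with a mean above the input. The share of N2 peaks (73.2%) was 44.2% with 0.5 of the MSTR-1 peak, 81.5% by gene, 47.5% at a fold of at least 4, 61.6% for a mean above the input and 59.9% without rRNA too. These rules differ by construction in what counts as shared. Pairs with a higher fold in N2 numbered 177 of 223, 72 with column totals and 175 to 179 with 1 CLIP library alone.

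The 13 lists became 6 at a deposited fold of at least 4 and 0 against genes with an N2 peak, where 7 infinite odds ratios gave no value. At the fold of at least 4 the odds ratio turned for oocyte regulators (0), ribosomal proteins (0.86) and splicing factors (0.93). Against N2 genes it turned for ribosomal proteins (0.55), muscle (0.29) and collagens (0.27). The cause was not tested.

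With 1 library alone, list medians relative to all genes ranged from 0.74 to 1.14 for collagens, 2.59 to 2.71 for histones, -1.03 to -0.53 for ribosomal proteins, 0.090 to 0.66 for muscle and -1.09 to -0.68 for vitellogenins. With at least 50 reads they were 1.16 for collagens, 3.62 for histones and -0.55 for ribosomal proteins. Pearson's r between libraries was 0.82 with a pseudocount of 0.5, 0.94 with 10, 0.96 with at least 50 reads (rho 0.92) and 0.82 without rRNA. Odds ratios of MSTR-1 against N2 peaks that no longer passed were 1.98 and 1.61 for protein-coding peaks, at a fold of at least 4 and per gene, and 1.47, 1.62 and 1.64 for chromosome III, at that fold, per gene and above the input.

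Of 77 named peaks 29 passed the threshold. edgeR lost 3 of these calls with the authors' scaling, where no named peak changed sign, and 10 with TMM. TMM placed glh-1 (-0.037), cgh-1 (-0.12), mex-5 (-0.015), nlp-27 (-0.14), hsp-4 (-0.14) and nspd-2 (-0.20) below the input on the log2 scale, and DESeq2 placed glh-1 (-0.010), cgh-1 (-0.086), nlp-27 (-0.12), hsp-4 (-0.11) and nspd-2 (-0.17) there. Column totals, which shift all peaks, ended 8 calls without a change of sign and turned 29 named peaks. Among called peaks these were emb-9 (-0.33), icl-1 (-0.32) and rps-27 (-0.82). The others were mstr-1 (-1.55), vit-5 (-0.85), vit-4 (-1.53), glh-1 (-1.66), cgh-1 (-1.74), mex-5 (-1.64), syp-2 (-1.36), rpl-41.1 (-0.65), rpl-6 (-1.06), rpl-38 (-1.17), eef-2 (-0.67), inf-1 (-0.93), ifc-2 (-0.99), asp-6 (-0.997), nlp-28 (-0.10), nlp-29 (-0.92), nlp-27 (-1.78), hsp-12.2 (-0.27), hsp-6 (-0.40), hsp-3 (-0.86), hsp-4 (-1.77), hrpk-1 (-1.18), snr-4 (-1.39), ssp-10 (-0.38), ssp-11 (-1.29) and nspd-2 (-1.83).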

Other observations

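The genes smd-1, azin-1, oaz-1, odc-1, spds-1, cut-2 and grl-16 were chosen after their values were seen, and no list holding them was tested. The gene smd-1 (S-adenosylmethionine decarboxylase) had 3 of 4 own peaks higher than the input by limma, with a mean fold of 3.91 over the gene, azin-1 (antizyme inhibitor) 2 of 3 at 3.03-fold, and oaz-1 (ornithine decarboxylase antizyme) 1 of 2 at 2.09-fold. The related genes odc-1 and spds-1 had 0 own peaks. edgeR called 2, 0 and 0 peaks of smd-1, azin-1 and oaz-1. The peak with the lowest adjusted p among these, over smd-1 (chromosome I, 14049967 to 14050292), had 78 and 129 reads against 9 in the input (mean fold 6.52, limma adjusted p = 1.23e-10, edgeR adjusted p = 6.30e-06), and none of the 9 own peaks of these genes overlapped an N2 peak. As only 8.75% of all MSTR-1 peaks had an N2 overlap, its absence at 9 peaks does not set these genes apart. The gene cut-2 (a cuticlin) had 3 of 3 higher at 5.06-fold and grl-16 5 of 6 at 4.05-fold, and N2 peaks overlapped 1 and 2 of their peaks. TMM called 1 peak of smd-1, 2 of cut-2 and 1 of grl-16.

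A list of fasting and fat metabolism genes, written after icl-1, pck-1 and acs-2 had been seen and so including them, had 17 of 45 own peaks higher and 0 lower by limma, and 3 higher with TMM. Its median over 12 genes was 0.24 above that of all genes, higher than 89.02% of matched random lists. icl-1 had 6 of 10 peaks higher with a mean fold of 2.50, and acs-2 3 of 5 at 5.75-fold. For icl-1 and acs-2, edgeR called 4 and 3 peaks with the authors' scaling, and 0 and 1 with TMM. A basement membrane list, written after emb-9, let-2 and mig-6 had been seen, had 10 of 67 peaks higher and 0 lower, 0 higher with TMM, and a median 0.14 above that of all genes at the percentile 76.9. Of its 16 genes only 7 had an own peak, and emb-9 (18), let-2 (19) and mig-6 (13) held most of the 67 peaks. The list did not stand clearly above other genes. In the mitochondrial genome 4 of 7 MSTR-1 peaks were higher than the input, all in the rRNAs and COX1. A called peak over KEF34_r01 (10735 to 10965) overlapped an N2 peak. The fold there was 18.5 in MSTR-1 CLIP (2 input reads) and 85.9 in N2 (1 input read). The called peak over KEF34_r02 did not pass with TMM (edgeR adjusted p = 0.071).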
